A study of Mus musculus with 4 samples.

How the data were processed

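Single-nucleus RNA sequencing was available for 4 libraries of mouse hypothalamus, 2 from mice given vehicle (vehicle 1 and vehicle 2) and 2 from mice given imidazole propionate (ImP 3 and ImP 4). Imidazole propionate is a product of histidine breakdown by gut bacteria. Per the labels' protocols, conventionally colonised C57BL/6J mice received 350 µg of ImP per day, or water with 1% DMSO as vehicle, over 2 weeks from an osmotic minipump in the peritoneal cavity. After perfusion the hypothalamus was taken out and snap-frozen, nuclei were isolated with a kit, about 10000 nuclei were loaded per 10x Genomics 3′ reaction, and at least 40000 read pairs per nucleus were aimed for.

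The deposited files hold whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger 8.0.1 against the mouse build GRCm39, per the submitters' processing notes, which also name Seurat 5.0.0. The annotation release, the handling of intronic reads and any filter beyond the barcode call are not given in the sources used here. Each file lists 33696 genes. A genome of another build was at hand and was not used, so no coordinates are given. Gene symbols are those of the files, where 26 symbols stand for more than 1 identifier.

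The 4 files held 11255, 13723, 15471 and 16348 barcodes for vehicle 1, vehicle 2, ImP 3 and ImP 4, with total UMI counts of 48060194, 49291659, 49508252 and 51945297. Nuclei with fewer than 500 genes or more than 5% of UMIs from mitochondrially encoded genes were left out. Doublets were scored with Scrublet, and the highest scores were removed at 0.8% per 1000 barcodes in the file, or 9.0%, 11.0%, 12.4% and 13.1%, which took 1013, 1507, 1915 and 2138 nuclei from the 4 libraries. After these filters 9911, 11537, 12858 and 13605 nuclei were kept. Kept counts were scaled to 10000 UMIs per nucleus and log-transformed, and 3000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 with 5 iterations were used in scanpy 1.11.5, with no integration across libraries. Neurons and other nuclei were each clustered again in the same way.

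Clusters were named from marker genes fixed before the data were examined, as were the groups, tests, gene lists, the rule for named genes and the alternative settings. A marker counted as detected when at least 10% of a cluster's nuclei had a UMI, and a cluster needed 3 detected markers. A cluster stayed unnamed when its best class led the next by under 0.05 of the marker score, when another class scored 0.7 or more, or when its top 10 genes held more markers of another class than of its own. These margins and the separate clustering of the other nuclei were set after a first clustering had been seen and before any comparison between groups. The clustering also moved slightly with the processor and the numerical libraries. Its environment was fixed for repeatability only, after class-level gene results of an earlier environment had been seen, and a different random seed was added as an alternative. Neuron clusters were called GABAergic or glutamatergic when the mean level of Slc32a1, Gad1 and Gad2 was above 2 times the summed level of Slc17a6, Slc17a7 and Slc17a8, or the reverse, and of both transmitters otherwise.

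Nuclei were not treated as replicates. UMI counts were summed per library and class, and those of the classes fixed beforehand that had at least 20 kept nuclei in every library were tested. ImP was compared with vehicle by the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors, genes filtered at a minimum count of 10, and Benjamini-Hochberg adjustment within the class at a threshold of 0.05. With 4 libraries in 2 groups, 2 residual degrees of freedom were left per gene before information was shared between genes. How much was shared differed between classes, so counts of passing genes do not rank the classes by size of effect. Levels are given as CPM of the summed UMI counts of a class. Standard errors of log2 fold changes were taken from the test statistic. The labels do not say that each library is a separate animal, so the p-values measure the spread between libraries. The difference of the ImP effect between GABAergic and glutamatergic nuclei was tested as an interaction with library as a block. Shares of nuclei were tested with edgeR on nuclei numbers, with the kept nuclei of the library as its size. Intervals of shares in single libraries are exact 95% binomial intervals and cover counting error only.

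The 30 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, where at least 3 members were measured, which gave 234 tests over 8 classes, and again with an estimated correlation and with fry. None of the 92 calls held with the estimated correlation, and 1 held with fry. Genes were named by a fixed rule. In neurons and in all nuclei together these were the 12 genes with the largest fold change in each direction among those past the threshold, parted between the groups and at a mean of 10 CPM or more, and in other classes the 5 largest. Where fewer than 5 genes passed, the 3 smallest p-values in each direction, among genes with a name and at a mean of 10 CPM or more, were named as values not past the threshold. A fixed set of stress, feeding and activity genes was named in neurons whatever the p, and up to 4 members past the threshold were named per list.

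The alternatives were DESeq2 1.42.0, other size factors, filters, doublet handling and clusterings, counts thinned to equal totals, removal of genes at least 10 times higher in another class, the library-name prefix as a block, and leaving out each library in turn. Each test was run first on simulated counts with known changes. Of 100 genes changed 2-fold, edgeR recovered 72 of those simulated in neurons among 19791 genes, 60 in astrocytes among 12183, 44 in oligodendrocyte precursors among 9241 and 41 in microglia among 4551. Of 100 genes changed 4-fold, it recovered 86, 96, 91 and 81 in the same simulations. A simulated list raised 1.5-fold was called in neurons, among 19814 genes, with the preset correlation and was not called with the estimated one (adjusted p = 0.0767 with an estimated correlation). Genes were simulated independently of each other, so these runs cannot test the preset correlation where genes move together. The simulated spread of a gene depended on its level alone, so recovery may be lower in the data. Genes were not tested by class in tanycyte-like, endothelial-like, mural-like, fibroblast-like and pituitary-like nuclei, because at least 1 library held under 20 of them. Newly formed oligodendrocyte-like nuclei and neurons of both transmitters were not among the classes fixed for these tests. Values of some single genes are not reported here.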

Results

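The question was how 2 weeks of imidazole propionate (ImP), a product of histidine breakdown by gut bacteria, altered the cells of the mouse hypothalamus. Single-nucleus counts were available for 2 vehicle libraries (vehicle 1 and vehicle 2) and 2 ImP libraries (ImP 3 and ImP 4). After filtering, 9911, 11537, 12858 and 13605 nuclei were kept, in that order of libraries. Both ImP libraries held more nuclei and fewer molecules per nucleus than both vehicle libraries, with median UMIs of 3553 and 2945 per kept nucleus in vehicle and 2615 and 2602 in ImP. The median share of mitochondrially encoded UMIs in kept nuclei was 1.00%, 1.35%, 1.30% and 1.10%. Over all barcodes before filtering, total UMIs per library lay between 48060194 and 51945297, and the 10 most abundant genes took 9.98%, 9.94%, 9.65% and 9.94% of UMIs. Transcripts of the pituitary hormones Gh (growth hormone) and Prl (prolactin) stood apart in the kept nuclei of ImP 4. There Gh was at 2123 CPM against 28.1, 7.45 and 27.7 CPM in vehicle 1, vehicle 2 and ImP 3, and Prl at 717 CPM against 8.15, 1.39 and 8.89 CPM.

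Most nuclei were neuron-like, and the class whose share changed with ImP was a rare one, fibroblast-like nuclei. Fibroblast-like nuclei, named from collagen and other meningeal and perivascular genes such as Dcn and Col1a2, made up 0.0706% and 0.0953% of kept nuclei in vehicle 1 and vehicle 2 and 0.482% and 0.515% in ImP 3 and ImP 4. These were 7, 11, 62 and 70 nuclei, with exact 95% binomial intervals of 0.0284 to 0.146%, 0.0476 to 0.171%, 0.370 to 0.618% and 0.401 to 0.650%. Their share rose by 2.57 on the log2 scale (SE 0.248, adjusted p = 3.0e-09 by edgeR over 12 classes), with both ImP libraries above both vehicle libraries. That SE is smaller than counting error alone would give for so few nuclei, so the SE and the p overstate the certainty. The exact intervals of both ImP libraries lay above those of both vehicle libraries, but they cover counting error only. Without vehicle 1 the log2 ratio was 2.37 and the adjusted p was 0.0859, against 1.97e-08 to 0.657 over all alternatives. The number of classes past the threshold was 0 without vehicle 1, 2 without vehicle 2 and 4 without ImP 3, and it stayed at 1 without ImP 4.

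The large classes held similar shares in the 4 libraries, and none of the following differences passed the test. Neuron-like nuclei made up 71.3%, 70.6%, 68.6% and 64.5% of kept nuclei in vehicle 1, vehicle 2, ImP 3 and ImP 4 (log2 ratio -0.09, adjusted p = 0.345, both ImP libraries lower), and without ImP 3 the ratio of -0.14 passed (adjusted p = 1.8e-04, range over the alternatives 1.8e-04 to 0.953). Astrocyte-like nuclei took 10.2%, 10.6%, 11.4% and 10.5% and oligodendrocyte-like nuclei 11.2%, 10.8%, 11.3% and 10.5%. Oligodendrocyte precursor-like nuclei lay at 3.04%, 3.06%, 3.23% and 3.12%. Microglia-like nuclei, the resident immune cells, made up 0.948%, 1.39%, 1.52% and 1.54% (log2 ratio 0.39, SE 1.95, adjusted p = 0.862, both ImP libraries higher). Without vehicle 2 their ratio was 0.69. With so large an SE, the test could not tell an unchanged microglia-like share from a raised one. Mural-like nuclei of the vessel wall (0.182%, 0.139%, 0.194% and 0.287%) and endothelial-like nuclei (0.182%, 0.217%, 0.264% and 0.198%) were rare. Pituitary-like nuclei numbered 6, 4 and 19 in vehicle 1, vehicle 2 and ImP 3 and 653 in ImP 4, or 0.0605%, 0.0347%, 0.148% and 4.80% of kept nuclei (log2 ratio 5.68, SE 3.13, adjusted p = 0.345). Without ImP 3 that ratio was 6.65 and passed (adjusted p = 6.4e-11, range over the alternatives 6.4e-11 to 0.953). Unnamed clusters held 2.35%, 2.31%, 2.37% and 3.02% of the nuclei, and without ImP 3 their ratio of 0.38 passed (adjusted p = 2.9e-04, range over the alternatives 2.9e-04 to 0.953).

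**Figure D1:**
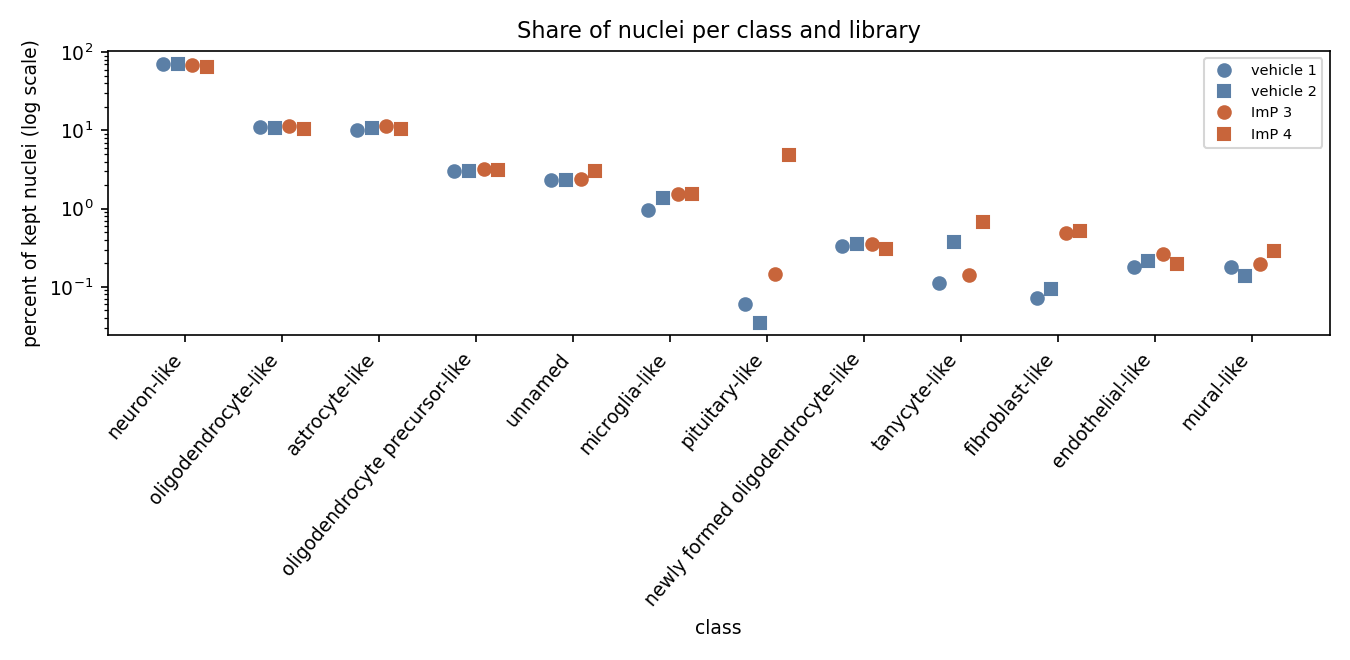
Share of kept nuclei per class (percent, log axis) in each of the 4 libraries, 1 point per library. Fibroblast-like nuclei lie at 0.0706% and 0.0953% in vehicle and at 0.482% and 0.515% in ImP, and pituitary-like nuclei reach 4.80% in ImP 4.

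In neuron-like nuclei, Mgp was the 1 gene past the threshold, and it lay higher in both ImP libraries in 3 glial classes too. Mgp encodes matrix Gla protein, a secreted inhibitor of calcification, and its level was 0.38 and 0.59 CPM in vehicle 1 and vehicle 2 and 5.43 and 5.48 CPM in ImP 3 and ImP 4. It rose by 3.51 on the log2 scale (SE 0.24, adjusted p = 0.0321 by edgeR, both ImP libraries higher). It was named after its values were seen because it lay under the expression minimum of the naming rule. The adjusted p of Mgp lay between 7.85e-05 and 0.0560 over 18 alternatives and passed in 16 of them, among them each fit without 1 library, and DESeq2 set no adjusted p for it. In all neuron-like nuclei of a library this came to 14, 21, 187 and 189 UMIs. Fibroblast-like nuclei, more frequent in ImP, carried Mgp at 0, 84.3, 485 and 615 CPM in the same order. In endothelial-like nuclei Mgp lay at 0, 86.2, 1600 and 235 CPM. In astrocyte-like nuclei it lay at 0.59, 2.37, 17.2 and 11.4 CPM (log2 ratio 3.23, adjusted p = 0.274). In oligodendrocyte-like nuclei it lay at 1.77, 1.18, 18.5 and 11.3 CPM (3.26, adjusted p = 0.268). In precursor-like nuclei, at 1.34, 0, 9.67 and 8.88 CPM, and in microglia-like nuclei, at 0, 5.06, 9.06 and 0 CPM, it was too low to be tested.

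Pmch and Hcrt, genes of lateral hypothalamic arousal and feeding peptides, had the smallest p after Mgp in neuron-like nuclei, without passing the test in the reported fit. Pmch, the precursor of melanin-concentrating hormone, lay at 162 and 154 CPM in vehicle and 265 and 302 CPM in ImP (log2 ratio 0.86, SE 0.08, adjusted p = 0.101), while Pmch in neuron-like nuclei passed without vehicle 2 (adjusted p = 0.00667), ImP 3 (5.03e-05) and ImP 4 (0.00241). Hcrt, the orexin precursor, lay at 66.8 and 72.0 CPM against 116 and 138 CPM (log2 ratio 0.89, SE 0.10, adjusted p = 0.273), and Sec11c, a subunit of the signal peptidase, had a log2 ratio of 0.71 at the same adjusted p. Hcrt in neuron-like nuclei passed without vehicle 2 (adjusted p = 0.0123), ImP 3 (1.1e-04) and ImP 4 (0.00708). Among lower genes at 10 CPM or more, the smallest p belonged to Cmss1 at -0.26, Rreb1 at -0.27 and Mccc2, an enzyme of leucine breakdown, at -0.31 (adjusted p = 0.290, 0.367 and 0.372). Each of these 6 genes had both ImP libraries on the same side of both vehicle libraries. By edgeR 1 of 20055 genes passed, 1438 had an unadjusted p under 0.05 (1199 higher and 239 lower in ImP, 1003 by chance), and DESeq2 called 275 genes, all higher in ImP. Leaving out vehicle 2 gave 251 calls, ImP 3 241 and ImP 4 4, and leaving out vehicle 1 gave 1.

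No stress-axis or activity gene of the fixed set passed the threshold in neuron-like nuclei in the reported fit, while Oxt, Pomc and Fkbp5 each passed without 1 library. Oxt (oxytocin) lay at 119, 180, 251 and 298 CPM in vehicle 1, vehicle 2, ImP 3 and ImP 4 (log2 ratio 0.89, SE 0.19, adjusted p = 0.275, and 1.24 at 0.00661 without vehicle 2) and Avp (vasopressin) at 199, 315, 337 and 475 CPM (0.68, SE 0.26, adjusted p = 0.645). Crh, the corticotropin-releasing hormone at the head of the stress axis, lay at only 2.87, 3.01, 3.25 and 4.70 CPM (0.45, adjusted p = 0.759, and 0.16 without ImP 4). Sst (somatostatin) had a ratio of 0.61 (adjusted p = 0.578, and 0.25 without ImP 4), with both ImP libraries above both vehicle libraries as for Oxt, Avp and Crh. Pomc, the precursor of melanocortins and of pituitary ACTH, lay at 28.1, 27.9, 36.8 and 190 CPM (2.04, SE 1.09, adjusted p = 0.856), and ImP 4, where it was highest, was the library with 653 pituitary-like nuclei. Without ImP 3 the ratio of Pomc was 2.80 and passed (adjusted p = 1.0e-09), and without ImP 4 it was 0.41 (adjusted p = 0.327). Trh (0.30, adjusted p = 0.855), Npy (0.52, 0.889) and Agrp (0.07, 0.922) had ratios of the other sign without ImP 4, at -0.05, -0.36 and -0.02. The glucocorticoid receptor gene Nr3c1 was level (0.00, adjusted p = 1.00) and its target Fkbp5 lay at 45.6, 39.7, 42.4 and 63.0 CPM (0.33, adjusted p = 0.802). The ratio of Fkbp5 was 0.60 without ImP 3 and passed (adjusted p = 0.0194), and 0.00 without ImP 4. The immediate early genes Fos (-0.32), Junb (-0.17), Nr4a1 (-0.13) and Egr1 (0.02), the imidazoline-binding protein gene Nisch (-0.03) and the histamine receptor gene Hrh3 (0.13) had adjusted p between 0.844 and 0.994. Without ImP 4 the ratio of Egr1 was -0.27 and that of Nr4a1 0.01, without vehicle 1 that of Nr4a1 was 0.24, without vehicle 2 that of Egr1 was -0.02 and without ImP 3 those of Nisch, Fos and Junb were 0.02, -0.02 and -0.01.

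With all nuclei of a library summed, Pmch and Hcrt had the smallest p among genes at 10 CPM or more, followed by Cped1. Mgp, under that level, had a smaller p (log2 ratio 3.91, adjusted p = 0.0676). For Pmch, Hcrt and Cped1 the log2 ratios were 0.89, 0.94 and 0.60 (adjusted p = 0.231, 0.289 and 0.289), and the lower genes Hs3st4, a heparan sulfate sulfotransferase, Mccc2 and Tro lay at -0.25, -0.30 and -0.24 (adjusted p = 0.303, 0.308 and 0.317). The 6 genes at 10 CPM or more had both ImP libraries on the same side of both vehicle libraries. Cped1 is among the fixed fibroblast markers, and its log2 ratio in neuron-like nuclei was 0.09 (adjusted p = 0.925 by edgeR). A sum over all nuclei also moves with the shares of the classes, and fibroblast-like nuclei were more frequent in ImP. Pmch in all nuclei together passed without ImP 3 (adjusted p = 5.3e-08) and ImP 4 (0.00649), and Hcrt in all nuclei together likewise (1.1e-07 and 0.0178). By edgeR 0 of 20928 genes passed, with 1846 at an unadjusted p under 0.05 (1543 higher, 303 lower, 1046 by chance), and DESeq2 called 390, all higher in ImP. The count was 81 without vehicle 2, 1103 without ImP 3 and 4 without ImP 4. Of the genes tested, 40.7% had both ImP libraries on the same side of both vehicle libraries, and in neuron-like nuclei 37.8%, where chance gives 1 in 3.

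GABAergic and glutamatergic neuron-like nuclei each had Mgp as their gene past the threshold. In GABAergic nuclei it lay at 0.50 and 0.67 CPM in vehicle and 5.65 and 6.46 CPM in ImP (log2 change 3.38, SE 0.29, adjusted p = 0.0254), and in glutamatergic nuclei at 0.27 and 0.46 CPM against 5.05 and 4.58 CPM (3.73, SE 0.33, adjusted p = 0.0344). In glutamatergic nuclei the call was lost without vehicle 1 (adjusted p = 0.642, range over the alternatives 5.9e-06 to 0.642). The next genes in GABAergic nuclei were Hcrt (1.03, adjusted p = 0.0564), Pmch (0.90, 0.0564) and Ndufa4, a respiratory chain gene (0.76, 0.144), and in glutamatergic nuclei Pmch (0.89, 0.0682), Hcrt (0.80, 0.215) and the myelin gene Mal (0.94, 0.229), all higher in both ImP libraries. Hcrt and Pmch in GABAergic nuclei passed in each fit without 1 library (adjusted p = 4.5e-05 to 0.0308 and 4.1e-05 to 0.0309). Pmch in glutamatergic neuron-like nuclei passed in those without vehicle 2, ImP 3 and ImP 4 (adjusted p = 0.0180, 0.00185 and 0.0172), as did Hcrt in glutamatergic neuron-like nuclei (0.0497, 4.6e-04 and 0.0306). Lower in both ImP libraries were Cmss1 (-0.24, adjusted p = 0.218), Hs3st4 (-0.22, 0.248) and the centrosomal gene Cep70 (-0.28, 0.251) in GABAergic nuclei, and Col16a1, a collagen (-0.46, 0.264), Cmss1 (-0.27, 0.290) and Wdr95 (-0.56, 0.301) in glutamatergic nuclei. By edgeR 1 of 17945 genes passed in GABAergic nuclei and 1 of 18328 in glutamatergic nuclei, with 1435 and 1277 at an unadjusted p under 0.05, and DESeq2, which set no adjusted p for Mgp, called 180 and 136. Without vehicle 1, vehicle 2, ImP 3 and ImP 4 in turn, the counts were 9, 399, 265 and 6 in GABAergic nuclei and 0, 62, 99 and 6 in glutamatergic nuclei.

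The log2 ratio of ImP to vehicle differed between GABAergic and glutamatergic nuclei for 11 of 18763 genes in a test of the interaction, 7 with the higher log2 change in GABAergic nuclei. Among them were the marker genes that set the classes apart. For Slc17a6, Gad1 and Gad2 the rise lay in the class that should lack the gene. A response to ImP particular to 1 class of neurons is therefore not shown. Slc17a6, the vesicular glutamate transporter, lay at 21.3, 22.2, 33.1 and 34.1 CPM in GABAergic nuclei of vehicle 1, vehicle 2, ImP 3 and ImP 4 and at 187, 185, 174 and 190 CPM in glutamatergic nuclei (difference of log2 changes 0.66, adjusted p = 1.1e-05). Gad2, an enzyme of GABA synthesis, went the other way, at 27.4, 31.0, 41.0 and 38.0 CPM in glutamatergic nuclei with a log2 change of 0.45 against 0.01 in GABAergic nuclei (difference -0.45, adjusted p = 0.0047). The others included Avp, Gh, Trh, Hbb-bs, Adcyap1, Gad1, Gm38505 and Dlx6os1, and Gh is a marker of the pituitary-like nuclei of ImP 4. There were 850 genes at an unadjusted p under 0.05, and DESeq2 called 1 gene. The count was 72 without vehicle 2 and 7 without ImP 4, 11 without vehicle 1 and 14 without ImP 3.

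Across gene lists fixed beforehand, genes of protein synthesis and of the respiratory chain lay higher in ImP as groups in neuron-like nuclei. The ribosomal protein genes had a median log2 ratio of 0.47, and all 77 measured had both ImP libraries above both vehicle libraries, where chance gives 1 in 3 for both directions together (camera adjusted p = 4.25e-85). Their adjusted p was 0.510 with an estimated correlation, and 0 of the 77 passed over all genes while 73 rose when adjusted over the list alone. Rpl21 (0.48), Rps25 (0.56), Rpl35a (0.56) and Rpl27 (0.51) had the smallest p, at an adjusted p of 0.273 over all genes by edgeR. The nuclear-encoded genes of oxidative phosphorylation had a median of 0.41 (adjusted p = 4.96e-62, and adjusted p = 0.510 with an estimated correlation). Of 73 measured members 63 lay higher and 1 lower in both ImP libraries, 0 passed over all genes, and 52 rose when adjusted over the list alone, among them Uqcrb (0.61), Ndufa4 (0.74), Ndufa6 (0.42) and Ndufb6 (0.50). The mitochondrially encoded genes of the same chain did not move with them, with a list call in GABAergic nuclei alone at a median of -0.07 (adjusted p = 0.0413, and adjusted p = 0.785 with an estimated correlation), lost without vehicle 2 (adjusted p = 0.756) and without ImP 4 (0.640). Depth moved with these groups, since both ImP libraries had fewer UMIs per neuron-like nucleus, with medians of 4595, 3861, 3487 and 3492.

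Peptide, chaperone and hormone-response lists also lay higher in ImP in neuron-like nuclei. Feeding and energy balance peptides had a median log2 ratio of 0.42 over 39 measured genes (adjusted p = 6.97e-19), and 9 members rose when adjusted over the list alone against 0 over all genes, among them Pmch, Hcrt, Gal (0.90) and Cartpt (0.67). The stress axis list had a median of 0.24 over 25 genes (adjusted p = 2.8e-06), with 3 members that rose when adjusted over the list alone and 0 over all genes, and Oxt, Nts (0.67) and Tac1 (0.48) among its smallest p. Heat shock and unfolded protein response genes had a median of 0.32 over 27 genes (adjusted p = 1.36e-12), with 4 members that rose when adjusted over the list alone and 0 over all genes, and the chaperones Hspe1 (0.55), Hspa8 (0.47), Hsp90ab1 (0.40) and Hsp90aa1 (0.37) among its smallest p. These 3 lists had an adjusted p = 0.608 with an estimated correlation. Glucocorticoid response genes had a median of 0.27 over 29 genes (adjusted p = 1.61e-05, and adjusted p = 0.510 with an estimated correlation). Of these 3 rose when adjusted over the list alone and 0 over all genes, and those of smallest p were the metallothioneins Mt1 (0.57) and Mt2 (0.63), Ddit4 (0.55) and Klf9 (0.32). The 38 measured synaptic vesicle genes had a median of 0.05 (adjusted p = 0.0365, and adjusted p = 0.889 with an estimated correlation), lost without vehicle 1 (adjusted p = 0.0868), vehicle 2 (0.126) and ImP 4 (0.504), with 1 member that rose when adjusted over the list alone and 0 over all genes.

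Lists named for other cell types moved in neuron-like nuclei as well, and these shifts are not shown to be changes in neuronal expression. RNA from other nuclei was not separated from neuronal RNA in the list tests. Mal, for example, was at least 10 times higher in another class than in glutamatergic nuclei. Myelin and oligodendrocyte lipid genes had a median log2 ratio of 0.43 over 29 genes (adjusted p = 7.81e-17), with 12 that rose when adjusted over the list alone and 0 over all genes, among them Opalin (0.96), Mal (0.85) and Scd2 (0.36). Microglial activation and inflammation genes had a median of 0.65 over 22 genes (adjusted p = 2.2e-13), with 8 that rose when adjusted over the list alone and 0 over all genes. Those of smallest p were the antigen presentation genes Cd74 (1.86) and H2-Aa (2.88), Spp1 (1.73) and the ferritin gene Fth1 (0.65). Reactive astrocyte genes had a median of 0.27 over 24 genes (adjusted p = 2.59e-05), with S100a10 (0.85) as the 1 that rose when adjusted over the list alone and 0 over all genes. Interferon response genes had a median of -0.04 with a mean of 0.19 and an upward call over 25 genes (adjusted p = 0.0492), lost without ImP 3 (adjusted p = 0.0755) and ImP 4 (0.138). There 3 genes rose when adjusted over the list alone and 0 over all genes, namely Psmb8 (1.53), H2-K1 (0.80) and B2m (0.85). All 4 lists had an adjusted p = 0.510 with an estimated correlation.

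**Figure D2:**
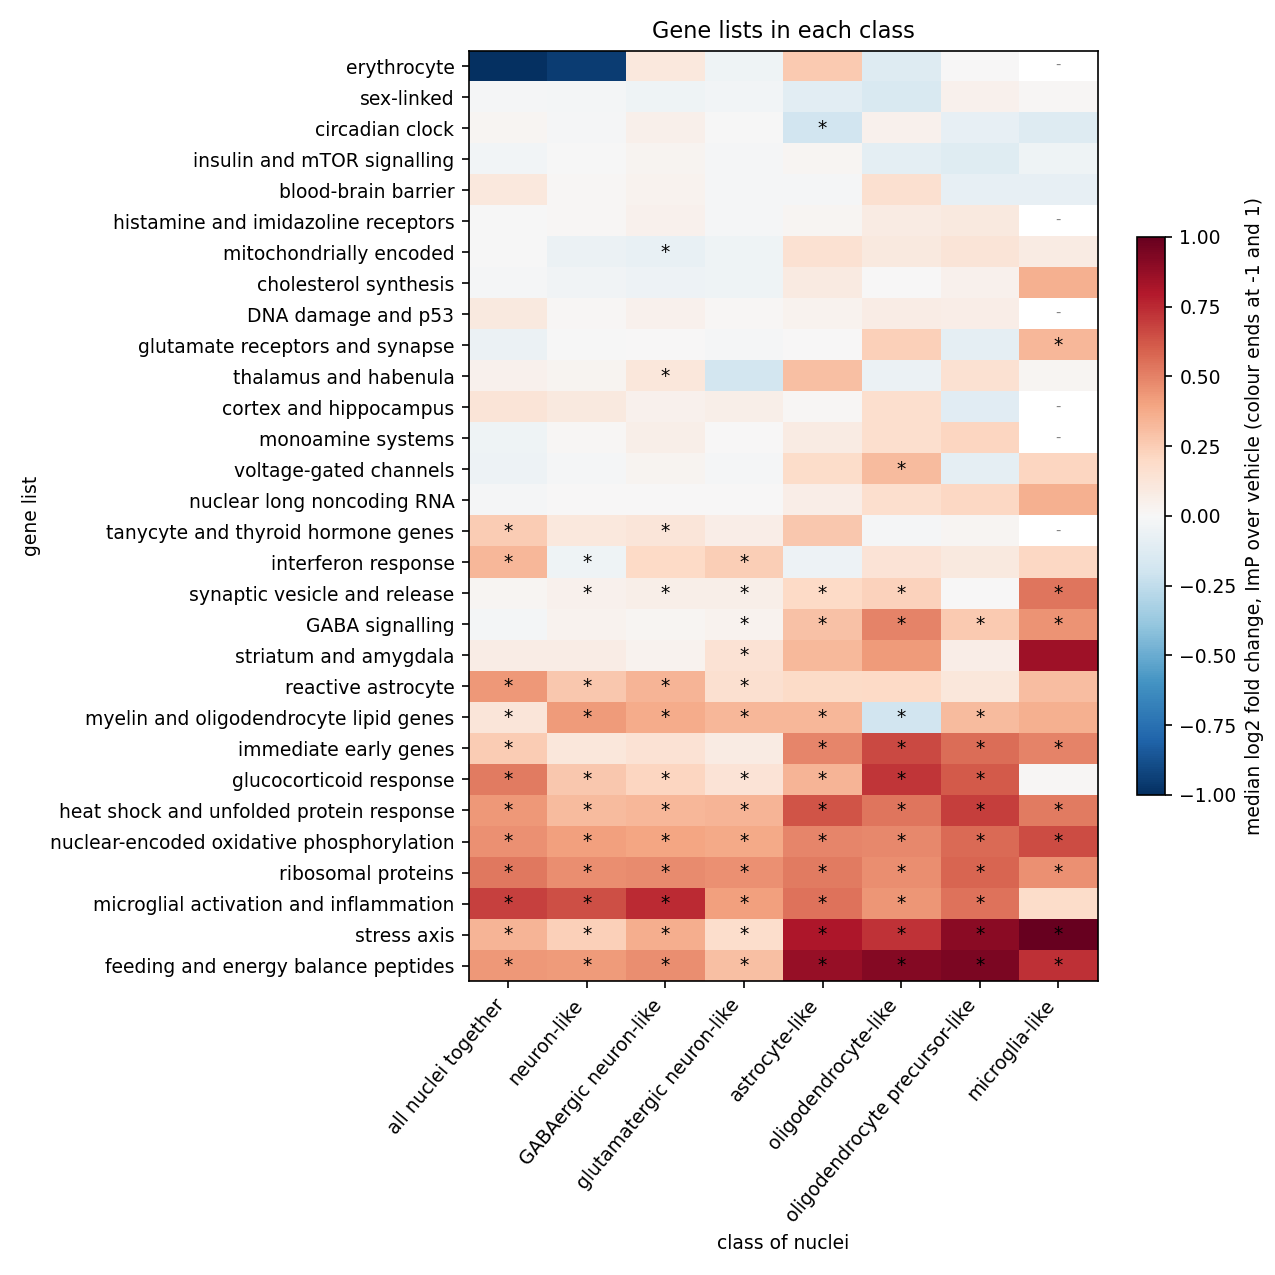
Median log2 ratio of ImP to vehicle (colour, ending at -1 and 1) for each fixed gene list (vertical axis) in each tested class (horizontal axis), with a star for a camera call at the preset correlation and a dash where a list was not tested. Ribosomal proteins lie between 0.45 and 0.59 and oxidative phosphorylation between 0.38 and 0.65 in all 8 classes.

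In astrocyte-like nuclei, Nenf and the neuronal peptide genes Hcrt and Pmch had the smallest p among higher genes at 10 CPM or more, and no gene passed the test. Nenf, a secreted neurotrophic factor, had a log2 ratio of 1.10, Hcrt of 1.04 and Pmch of 0.79, and the lower genes were Smad3, a mediator of TGF-beta signalling, and Elmo2 at -0.72 each and Rpa1 at -0.69 (adjusted p = 0.274 to 0.275), all with both ImP libraries on the same side. In oligodendrocyte-like nuclei the smallest p at 10 CPM or more belonged to Cartpt, a feeding peptide (1.20), Tm2d3 (1.13) and the signal peptidase gene Spcs1 (1.00), each at an adjusted p of 0.268, and to the lower genes Lcp1, an actin-bundling protein (-1.33), Fancc (-0.73) and Prkcz (-0.61), each at 0.286. Within both classes ImP 4 stood apart, because cluster 54 held 1277 of its astrocyte-like nuclei against 10, 26 and 29 in vehicle 1, vehicle 2 and ImP 3, and cluster 58 held 1262 of its oligodendrocyte-like nuclei against 0, 13 and 15. The genes that set both clusters apart most from the others of their class were those of pituitary hormones, Cga, Prl, Gh and Pomc, followed by Zbtb16 in cluster 54 and Sgk1 in cluster 58. By edgeR 0 of 12463 genes passed in astrocyte-like nuclei (1302 at an unadjusted p under 0.05, DESeq2 0) and 0 of 11684 in oligodendrocyte-like nuclei (1292 at an unadjusted p under 0.05, DESeq2 11). Without vehicle 1, vehicle 2, ImP 3 and ImP 4 in turn, the counts were 8, 610, 352 and 3 in astrocyte-like nuclei and 0, 0, 483 and 12 in oligodendrocyte-like nuclei.

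The gene lists of astrocyte-like and oligodendrocyte-like nuclei, most of them in clusters 54 and 58 in ImP 4, moved upward for peptides, ribosomes and respiration. Feeding peptides had medians of 0.87 over 26 genes in astrocyte-like nuclei (adjusted p = 1.08e-17) and 0.92 over 22 genes in oligodendrocyte-like nuclei (adjusted p = 9.99e-21), with 13 and 14 that rose when adjusted over the list alone and 0 over all genes. Ribosomal protein genes had medians of 0.52 (adjusted p = 1.88e-35) and 0.47 (2.88e-28), with 62 and 39 of 76 adjusted over the list alone. Oxidative phosphorylation had medians of 0.48 in both (1.5e-26 and 1.43e-25), with 33 and 29 of 73 adjusted over the list alone. The stress axis (0.81 and 0.72) and heat shock lists (0.63 and 0.54) were called too, with 7 and 5 and with 9 and 2 members that rose when adjusted over the list alone. Those 5 lists had an adjusted p = 0.576 with an estimated correlation in astrocyte-like nuclei and 0.498 to 0.565 in oligodendrocyte-like nuclei. Immediate early genes had medians of 0.49 and 0.66 (adjusted p = 3.66e-06 and 4.38e-07), and adjusted p = 0.576 and 0.498 with an estimated correlation. Of these, 5 of 19 rose when adjusted over the list alone in astrocyte-like and 6 of 19 in oligodendrocyte-like nuclei, 0 over all genes.

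Glucocorticoid response genes were called in both of these glial classes, in astrocyte-like nuclei only with ImP 4. The list had a median log2 ratio of 0.71 over 23 genes in oligodendrocyte-like nuclei (adjusted p = 2.32e-08, and adjusted p = 0.498 with an estimated correlation), with 8 that rose when adjusted over the list alone and 0 over all genes, and without ImP 4 the call remained (adjusted p = 0.00681). In astrocyte-like nuclei the median was 0.34 over 20 genes (adjusted p = 0.00733, and adjusted p = 0.633 with an estimated correlation), with 0 members adjusted over the list alone, and without ImP 4 the adjusted p was 0.970. Fkbp5, a co-chaperone of the glucocorticoid receptor, lay at 31.2, 71.8, 43.2 and 184 CPM in oligodendrocyte-like nuclei of vehicle 1, vehicle 2, ImP 3 and ImP 4, and Sgk1, a glucocorticoid-induced kinase, at 214, 226, 385 and 742 CPM. In ImP 4 clusters 54 and 58 held most nuclei of these classes, and 653 pituitary-like nuclei were present.

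**Figure D3:**
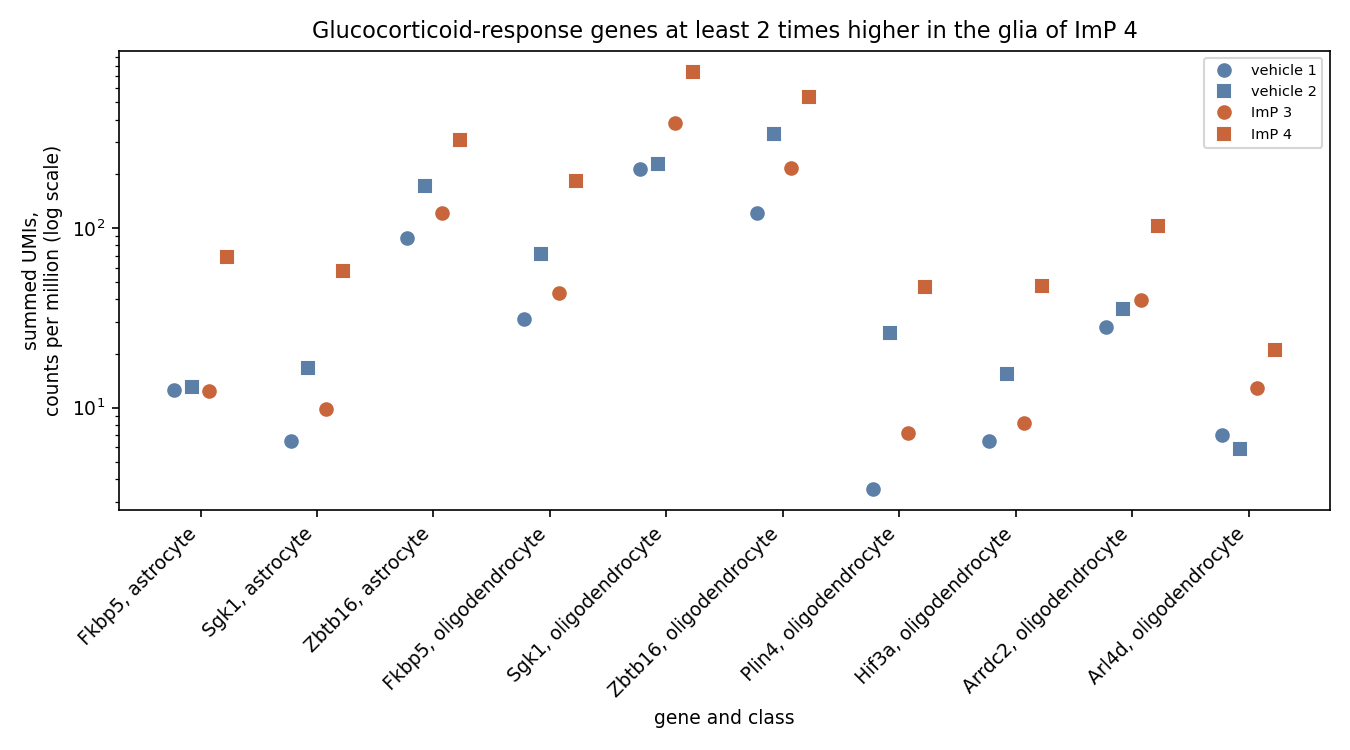
CPM (log axis) of the glucocorticoid response genes that lay at least 2 times higher in ImP 4 than in the mean of the other libraries, in astrocyte-like or oligodendrocyte-like nuclei, 1 point per library. Fkbp5 in oligodendrocyte-like nuclei lies between 31.2 and 71.8 CPM in the other 3 libraries and at 184 CPM in ImP 4.

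Myelin genes went down as a group in oligodendrocyte-like nuclei, where they are made, and other lists of the 2 glial classes were mixed. The myelin list had a median log2 ratio of -0.19 over 29 genes in oligodendrocyte-like nuclei (adjusted p = 0.0169, and adjusted p = 0.512 with an estimated correlation), lost without vehicle 1 (adjusted p = 0.0907) and ImP 4 (0.283), with 0 members past the threshold over all genes or adjusted over the list alone. In astrocyte-like nuclei its median was 0.33 (adjusted p = 0.0113, and adjusted p = 0.633 with an estimated correlation), lost without vehicle 1 (adjusted p = 0.188) and ImP 3 (0.692). Circadian clock genes had a median of -0.19 over 19 genes in astrocyte-like nuclei (adjusted p = 0.0132, and adjusted p = 0.576 with an estimated correlation), lost without vehicle 1 (adjusted p = 0.188). GABA signalling had medians of 0.29 in astrocyte-like nuclei (adjusted p = 0.0132), lost without vehicle 1 (adjusted p = 0.182) and ImP 4 (0.0520), and 0.49 in oligodendrocyte-like nuclei (3.46e-08), where 8 of 24 genes rose when adjusted over the list alone. Those GABA signalling calls had adjusted p = 0.576 and 0.498 with an estimated correlation. Voltage-gated channel genes were called in oligodendrocyte-like nuclei at a median of 0.32 over 29 genes (adjusted p = 0.00198, and adjusted p = 0.498 with an estimated correlation). Synaptic vesicle genes had medians of 0.20 in astrocyte-like and 0.23 in oligodendrocyte-like nuclei (adjusted p = 1.68e-04 and 5.25e-05, and adjusted p = 0.633 and 0.498 with an estimated correlation). Microglial activation genes had medians of 0.54 and 0.44 (adjusted p = 2.23e-05 and 4.96e-04, and adjusted p = 0.576 and 0.498 with an estimated correlation). In ImP 4 most of these nuclei lay in clusters 54 and 58.

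Oligodendrocyte precursor-like nuclei had the most changed genes of the 8 classes in the reported edgeR fit, 66 that rose and 2 that fell of 9617. That count does not rank the classes by size of effect, since each fit shared a different amount of information between genes. Hcrt in neuron-like nuclei did not pass at 0.89 (SE 0.10, adjusted p = 0.273 by edgeR). Its ratio was larger relative to its SE than that of Nenf in precursors. Nenf rose from 44.1 and 40.3 CPM in vehicle to 94.3 and 121 CPM in ImP (log2 change 1.35, SE 0.23, adjusted p = 0.00344), and Ptgds, a prostaglandin D synthase, from 148 and 240 CPM to 410 and 528 CPM (1.27, SE 0.20, adjusted p = 0.00464). Nenf and Ptgds stayed past the threshold without each library in turn, but Nenf in oligodendrocyte precursor-like nuclei was lost at a limit of 1% mitochondrial UMIs (adjusted p = 0.0627) and Ptgds with DESeq2 (0.111). S1pr1, a sphingosine 1-phosphate receptor, rose by 2.31 (SE 0.57, adjusted p = 0.0354), C1galt1c1, a chaperone of glycosylation, by 1.45 (adjusted p = 0.0374) and Rwdd2a by 1.63 (adjusted p = 0.0474). Midn, a protein of proteasomal degradation, fell by 1.27 (SE 0.32, adjusted p = 0.0385), from 48.1 and 41.6 CPM to 19.3 and 17.8 CPM, and Gm38505 was the other gene that fell. All 6 named genes had both ImP libraries on the same side of both vehicle libraries, and Ptgds and S1pr1 were at least 10 times higher in another class. At an unadjusted p under 0.05 there were 971 genes, and DESeq2 called 13, all of them among the 68 and fewer than its 390 in all, 275 in neuron-like, 180 in GABAergic and 136 in glutamatergic nuclei. The count was 3 without vehicle 1, 222 without vehicle 2, 129 without ImP 3 and 35 without ImP 4, of which 3, 64, 54 and 24 were among the 68. S1pr1 was lost without each library in turn (adjusted p = 0.150 to 0.442), Rwdd2a without vehicle 1 (0.580) and ImP 4 (0.819), C1galt1c1 without vehicle 1 (0.207), vehicle 2 (0.153) and ImP 4 (0.514), and the fall of Midn in oligodendrocyte precursor-like nuclei without vehicle 1 (0.443), ImP 3 (0.0745) and ImP 4 (0.288).

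By list, the genes that rose in oligodendrocyte precursor-like nuclei included ribosomal, respiratory chain, chaperone and neuropeptide genes. Ribosomal protein genes had a median log2 ratio of 0.59, 11 of 76 rose over all genes and 55 when adjusted over the list alone, such as Rpl35a (0.88) and Rpl41 (0.81). Oxidative phosphorylation had a median of 0.56, with 7 of 73 that rose over all genes and 29 adjusted over the list alone, such as Ndufc2 (1.06), Cox4i1 (0.83) and Ndufb3 (1.18). Feeding peptides had a median of 0.94, and 4 of 17 rose over all genes and 10 adjusted over the list alone, with Hcrt (0.93), Pmch (0.78), Tac1 (1.05) and Nts (1.13). The stress axis list had a median of 0.90, and 3 of 12 rose over all genes, Tac1, Oxt (0.93) and Nts, and 6 adjusted over the list alone. Heat shock genes had a median of 0.69, and 3 of 19 rose over all genes, Hsp90ab1 (0.75), Hsp90aa1 (0.77) and Hspa8 (0.71), and 10 adjusted over the list alone. Camera adjusted p for these 5 lists lay between 7.25e-42 and 1.55e-09, with adjusted p = 0.498 to 0.588 with an estimated correlation. Glucocorticoid response genes had a median of 0.61 (adjusted p = 4.17e-05, and adjusted p = 0.498 with an estimated correlation), lost without ImP 4 (adjusted p = 0.149), with Mt1 (0.82) as the 1 of 13 that rose over all genes and 2 adjusted over the list alone. Genes at least 10 times higher in another class took 1.90%, 1.96%, 2.00% and 2.54% of the UMIs of this class in vehicle 1, vehicle 2, ImP 3 and ImP 4. The rises of the peptide genes are not shown to be changes in precursor expression. Hcrt made up 30.2, 28.7, 30.9 and 32.5% of the UMIs of Hcrt and Pmch together here. In neuron-like nuclei it made up 29.2 to 31.9%.

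**Figure D4:**
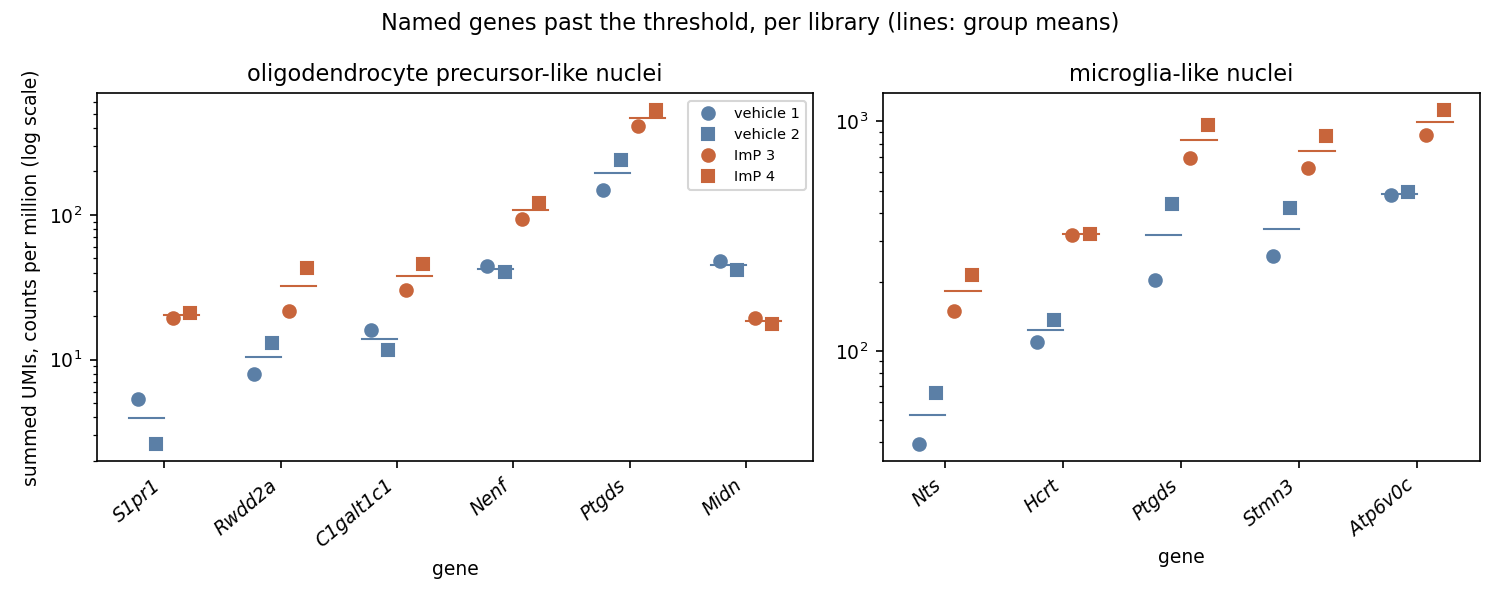
CPM (log axis) per library of genes past the threshold in oligodendrocyte precursor-like and microglia-like nuclei, 1 point per library, with lines at the group means. Nenf in precursors lies at 44.1 and 40.3 CPM in vehicle and at 94.3 and 121 CPM in ImP, and Midn is the gene that lies lower in ImP.

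In microglia-like nuclei 8 of 4973 genes rose and 0 fell, among them the peptide genes Hcrt, Nts, Oxt and Avp. Hcrt rose from 109 and 136 CPM in vehicle to 321 and 323 CPM in ImP (log2 change 1.37, SE 0.27, adjusted p = 0.0243), and Nts, the neurotensin precursor, from 39.1 and 65.7 CPM to 149 and 215 CPM (1.74, SE 0.37, adjusted p = 0.0410). Ptgds (1.33), Atp6v0c, a subunit of the proton pump of acidic organelles (1.05), and Stmn3, a tubulin-binding neuronal protein (1.11), rose as well (adjusted p = 0.0243, 0.0243 and 0.0314), and the other 3 were Oxt (1.02), Avp (0.91) and Ly6h (0.96). Named here were the 5 largest changes, and Oxt, Avp and Ly6h were named after their values were seen. All 8 had both ImP libraries higher, and genes at least 10 times higher in another class, Ptgds among them, took 2.59%, 2.998%, 2.93% and 4.58% of the microglial UMIs in vehicle 1, vehicle 2, ImP 3 and ImP 4. That rule compares whole classes and did not mark Hcrt, which neuron cluster 36 held at 1737 to 2918 CPM. The rises of the peptide genes are therefore not shown to be changes in microglial expression. There were 582 genes at an unadjusted p under 0.05, and DESeq2 called 0. Without vehicle 1 and without ImP 4 the count was 0, without vehicle 2 63 and without ImP 3 41. Without vehicle 1 the adjusted p was 0.0882 for Hcrt, 0.120 for Nts, 0.112 for Ptgds, 0.219 for Stmn3 and 0.0615 for Atp6v0c in microglia-like nuclei, and without ImP 4 it was 0.153, 0.403, 0.168, 0.403 and 0.277.

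The lists called in microglia-like nuclei did not include the microglial ones. Microglial activation genes had a median log2 ratio of 0.18 (adjusted p = 0.463) and glucocorticoid response genes of 0.01 (adjusted p = 0.187). The stress axis list had a median of 1.02 over 9 genes (adjusted p = 4.19e-08), with 3 that rose over all genes and 4 adjusted over the list alone, and feeding peptides a median of 0.73 over 11 genes (6.84e-09), with 2 that rose over all genes and 5 adjusted over the list alone. Oxidative phosphorylation (0.65, adjusted p = 6.65e-17), ribosomal proteins (0.45, 1.4e-17), heat shock (0.52, 3.93e-06), synaptic vesicle genes (0.53, 4.91e-05) and GABA signalling (0.45, 7.03e-04) were called as well. These 7 lists had adjusted p = 0.465 to 0.522 with an estimated correlation. Immediate early genes (0.50, adjusted p = 0.0280) and glutamate receptor genes (0.33, 0.0341) had adjusted p = 0.531 with an estimated correlation, and were lost without vehicle 1 (adjusted p = 0.431 and 0.347) and ImP 4 (0.748 and 0.468). GABA signalling was the 1 list in any class that passed with fry (adjusted p = 0.0359).

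Over the 8 classes, 92 of 234 pairs of a list and a class were called with camera at the preset correlation, 89 upward and 3 downward, 0 with an estimated correlation and 1 with fry. In all nuclei together the calls included ribosomal proteins (median log2 ratio 0.52), oxidative phosphorylation (0.46), feeding peptides (0.43), stress axis (0.34), heat shock (0.43), glucocorticoid response (0.52), microglial activation (0.69), reactive astrocyte genes (0.43) and myelin genes (0.12), each at an adjusted p = 0.696 with an estimated correlation. The myelin call was lost without ImP 3 (adjusted p = 0.143). Immediate early genes (0.26, adjusted p = 3.01e-04), interferon response (0.33, 3.03e-04) and tanycyte genes (0.25, 0.00274) were called there too, at an adjusted p = 0.699 with an estimated correlation. Immediate early genes lost the call without vehicle 2 (adjusted p = 0.115) and ImP 4 (0.670), and tanycyte genes without vehicle 1 (0.199) and ImP 4 (0.389). Immediate early genes had no call in neuron-like nuclei, at a median of 0.11 (adjusted p = 0.230). In precursors they had a median of 0.56 (adjusted p = 0.0295, and adjusted p = 0.751 with an estimated correlation), lost without vehicle 1 (adjusted p = 0.261) and ImP 4 (0.533). Thalamus and habenula genes were called in GABAergic nuclei (0.11, adjusted p = 0.0468, and adjusted p = 0.626 with an estimated correlation) and striatum and amygdala genes in glutamatergic nuclei (0.15, adjusted p = 0.0357, and adjusted p = 0.760 with an estimated correlation). Both were lost without vehicle 1 (adjusted p = 0.408 and 0.506) and ImP 4 (0.739 and 0.307).

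Other lists, among them insulin signalling and histamine receptors, had no call in any class in the reported fit. In neuron-like nuclei insulin and mTOR signalling, a pathway that ImP has been tied to in liver, had a median log2 ratio of -0.01 with a mean of 0.05 and an upward direction (adjusted p = 0.638). Histamine and imidazoline receptor genes had a median of 0.01 (adjusted p = 0.703), monoamine systems 0.01 (0.638), blood-brain barrier genes 0.01 (0.549), cholesterol synthesis -0.03 (0.598) and DNA damage genes 0.01 (0.589). Nuclear long noncoding RNA had a median of 0.01 and cortex and hippocampus genes of 0.10 (adjusted p = 0.903 each). Erythrocyte genes had a median of -0.95 (adjusted p = 0.903), and sex-linked genes a median of -0.02 with a mean of 0.11 and an upward direction (adjusted p = 0.981). Erythrocyte genes were called without vehicle 1 (adjusted p = 0.00580) and vehicle 2 (1.2e-09), and cholesterol synthesis without vehicle 1 (0.0137) and vehicle 2 (7.8e-04). Both lists had differing directions over the fits without 1 library.

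Of 36 neuron clusters tested, 27 had at least 1 changed gene, with 387 rises and 31 falls in 418 calls over 335088 tests, and 21481 of these tests had an unadjusted p under 0.05, against 16754 by chance. The gene called in the most clusters was Cst3, which rose in 20, followed by Pmch and Ptgds in 17 each, Atp6v0c in 13, Apoe in 11, Oxt in 10 and Fth1, Hcrt and Ndufa4 in 9 each. None of these fell in any cluster. They were picked by this tally after their values were seen. All clusters were cut from the same 4 libraries, so a shift of a whole library can recur in each, and the tally is not repeated evidence. Ptgds lay at 6654 CPM in fibroblast-like nuclei, against 74.8 to 270 CPM in the neuron-like nuclei of single libraries. Cluster 18 had the most, 82 rises and 8 falls, followed by cluster 4 with 65 and 2 and cluster 6 with 42 and 4. The share of neuron-like nuclei per cluster did not change for any of 38 clusters by edgeR, with 3 at an unadjusted p under 0.05. The smallest p belonged to cluster 1, at a log2 ratio of -0.52 (adjusted p = 0.208), and clusters 18 and 20 lay at 0.63 and -0.67 (adjusted p = 0.430 each). GABAergic clusters held 45.1%, 47.2%, 45.7% and 49.1% of neuron-like nuclei and glutamatergic clusters 47.3%, 45.1%, 48.3% and 43.2% in vehicle 1, vehicle 2, ImP 3 and ImP 4.

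Peptide genes stood out less in the neuron cluster with the highest level of each than in glia. Hcrt lay at 1921, 1737, 2918 and 2812 CPM in cluster 36 of vehicle 1, vehicle 2, ImP 3 and ImP 4 (log2 ratio 0.65) and at 137, 159, 251 and 348 CPM in astrocyte-like nuclei (1.02). Oxt lay at 1809, 1973, 2126 and 1629 CPM in cluster 28 (-0.01) and at 235, 420, 568 and 751 CPM in astrocyte-like nuclei (1.01), of which cluster 54 held most in ImP 4. Avp in cluster 28 and Pmch in cluster 32 had ratios of 0.01 and 0.38, against 0.75 and 0.77 in astrocyte-like nuclei, and Pomc, in cluster 22, of -0.16 against 2.89. Pomc lay at 528, 438, 216 and 650 CPM in cluster 22 and at 31.5, 48.6, 81.3 and 513 CPM in astrocyte-like nuclei, so both its ratios leaned on ImP 4. These ratios of group means were not tested, and in cluster 32 vehicle 2 had only 14 nuclei.

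**Figure D5:**
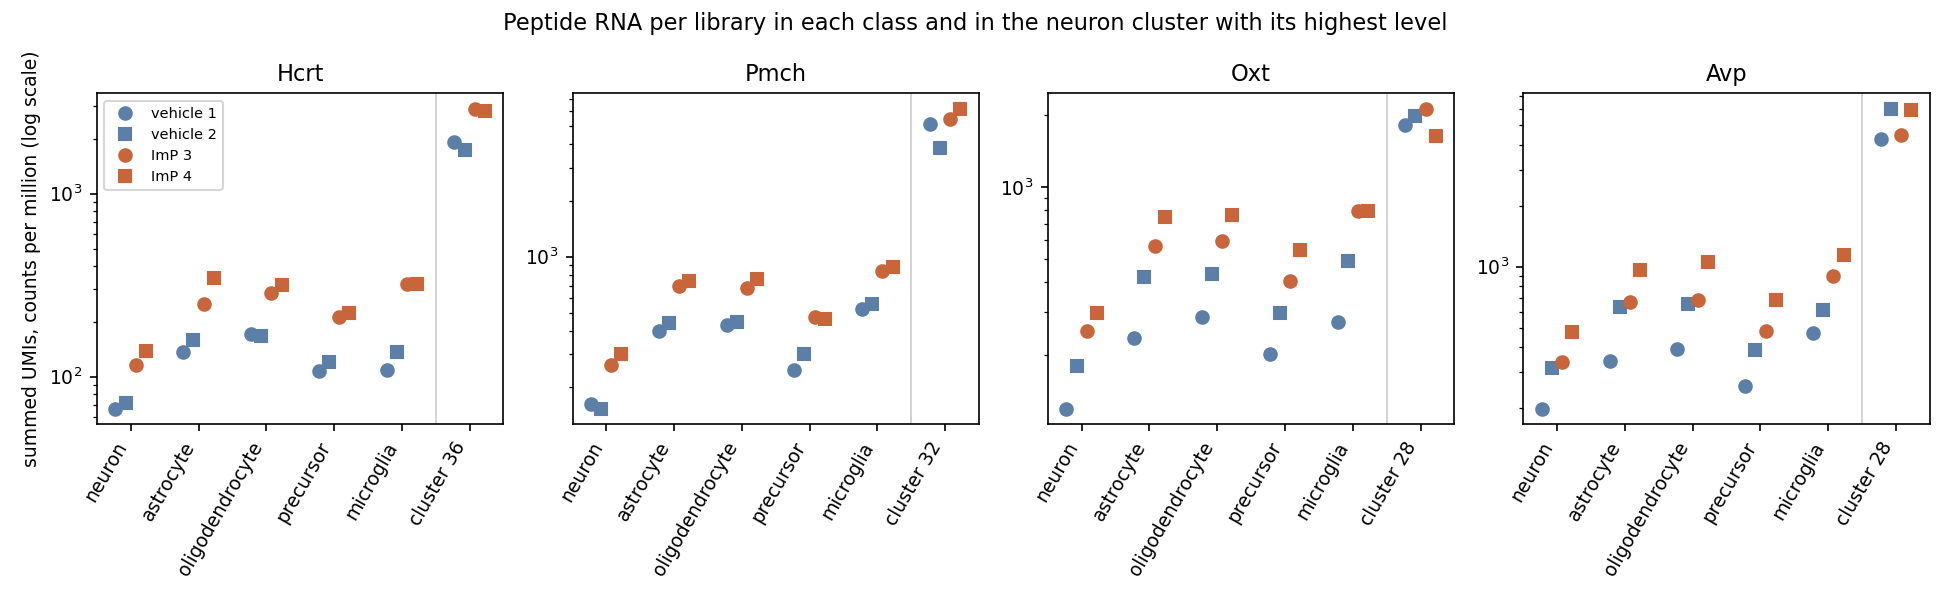
CPM (log axis) of Hcrt, Pmch, Oxt and Avp in each class and in the neuron cluster with the highest level of each, 1 point per library. Hcrt lies at 66.8 and 72.0 CPM in vehicle and 116 and 138 CPM in ImP in neuron-like nuclei, and the Oxt values of cluster 28 overlap between the groups.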

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

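Of the tests reported here, those of the ImP treatment for glial glucocorticoid genes, of blood vessel and of the base of the brain for fibroblast-like nuclei, and both tests of fibroblast RNA for Mgp were chosen only after the result had been seen. The gene choice of the treatment test, and the reading of the fibroblast test over 207 genes, were also changed after their values were seen, which turned both from an exclusion into an open result, and the vessel test was split, which turned it from open into an exclusion of unchanged proportions alone.

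The log2 ratio of ImP to vehicle differed between GABAergic and glutamatergic nuclei for 11 genes in the interaction test of edgeR. The log2 change was higher in GABAergic nuclei by 0.66 for Slc17a6, 0.38 for Avp, 1.09 for Gh, 0.76 for Trh, 4.16 for Hbb-bs and 0.66 for Adcyap1. It was lower there, with differences of -0.45 for Gad2, -0.60 for Gad1, -0.35 for Gm38505 and -0.86 for Dlx6os1. Adjusted p of these genes lay between 1.1e-05 for Slc17a6 and 0.0107 for Gm38505 and Dlx6os1. For Slc17a6, Gad1, Gad2 and Dlx6os1, markers of the transmitter classes, the log2 ratio in the class that should lack the gene was 0.65, 0.62, 0.45 and 0.72, none past the threshold there. These differences are therefore not shown to be effects of ImP on 1 type of neuron. Gh had log2 ratios of 6.75 in GABAergic and 5.63 in glutamatergic nuclei (adjusted p = 0.808 and 0.876), and stood at 8.60, 2.67, 21.8 and 1158 CPM in GABAergic nuclei of vehicle 1, vehicle 2, ImP 3 and ImP 4. Hemoglobin Hbb-bs stood at 9.27 CPM in glutamatergic nuclei of vehicle 1 and at 0.17, 0.23 and 0.87 CPM in the other 3. The number of such genes was 72 without vehicle 2 and 7 without ImP 4, and DESeq2 called 1.

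Genes of peptides, oxidative phosphorylation and ribosomal proteins lay higher in ImP in every class tested. Higher expression in the peptide neurons was argued against for the 5 peptides Hcrt, Pmch, Oxt, Avp and Pomc as a set, not for each. Their median log2 ratio was 0.0077 in the neuron cluster with the highest level of each and 1.01 in astrocyte-like nuclei. Oxt and Avp shared cluster 28, and the astrocyte-like level of Pomc was raised most in ImP 4. For Hcrt (0.65) and Pmch (0.38) it stayed open, as both ImP libraries lay above both vehicle libraries in their own clusters. More free RNA in the ImP libraries could not be settled, because the median of genes at least 10 times higher in another class was 0.0513 in the lowest of 4 glial classes and 0.12 to 0.25 in the others, against -0.0204 to -0.0021 for the remaining genes. In microglia-like nuclei the median against the vehicle mean was -0.0188 in ImP 3 and 0.4576 in ImP 4, so the rise there rested on ImP 4. The medians of ImP 3 and ImP 4 were 0.077 and 0.0776 in astrocyte-like and 0.1591 and 0.218 in oligodendrocyte-like nuclei. In precursor-like nuclei they were 0.0195 and 0.0801. The rule of 10 times compares whole classes and did not mark Hcrt or Pmch in astrocyte-like nuclei. Fewer UMIs per nucleus may contribute in part, because the median of the 3 lists fell from 0.42 to 0.2415 among neuron-like nuclei of 2000 to 4000 UMIs, and vehicle 2, with fewer UMIs per nucleus, lay above vehicle 1 by 0.25 over the same genes. Hcrt made up 29.2 to 31.9% of the UMIs of Hcrt and Pmch together in neuron-like nuclei. In astrocyte-like nuclei it made up 25.6, 26.5, 26.5 and 32.0% in vehicle 1, vehicle 2, ImP 3 and ImP 4. The interval of ImP 4 (30.036 to 33.979%) lay above those of the other libraries there. Astrocyte-like and neuron-like intervals overlapped in vehicle 1 and ImP 4 but not in vehicle 2 or ImP 3. Precursor-like intervals overlapped the neuron-like ones in every library, and oligodendrocyte-like intervals in all but vehicle 2. These intervals cover the counting of UMIs only, as if each UMI were drawn independently. In microglia-like nuclei Hcrt made up 17.3 and 19.6% in vehicle and 27.7 and 26.7% in ImP. Those intervals overlapped (9.78 to 27.3%, 13.3 to 27.2%, 22.3 to 33.7% and 21.8 to 32.1%).

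Glucocorticoid response genes, with list medians of 0.34 in astrocyte-like and 0.71 in oligodendrocyte-like nuclei of ImP to vehicle, were weighed on 7 genes in 10 pairs of gene and class chosen for lying at least 2 times higher in ImP 4, a choice that sets their median of 1.70 to vehicle high. Free RNA in the proportions of the pituitary-like nuclei of ImP 4 was argued against for these pairs as a set. The excess as a share of the pituitary-like level was on median 11.936 times that of Gh (range 1.06 to 236). It lay above the whole pituitary-like level in 7 of 10 pairs. For Fkbp5 this source stayed open. Its excess was 12.8% of that level in astrocyte-like and 30.4% in oligodendrocyte-like nuclei, against 12.1% and 12.6% for Gh. Free pituitary RNA in other proportions was not tested. The ImP treatment as a cause shared by both ImP libraries stayed open. Over 13 pairs chosen without ImP 3 the median log2 ratio to vehicle was -0.048 in ImP 3 (95% bootstrap interval -0.21 to 0.63) against 1.62 in ImP 4. That interval was drawn over the 13 pairs of gene and class and leaves out the spread between libraries. However, oligodendrocyte-like nuclei kept the list call without ImP 4 at the preset correlation. No list was called in oligodendrocyte-like nuclei with an estimated correlation. A raised glucocorticoid level in the tissue of ImP 4 is a candidate explanation. The 7 genes lay higher there by a median of 0.3485 in neuron-like, 0.99 in precursor-like and 0.85 in microglia-like nuclei. Plin4 went the other way in neuron-like (-0.15) and microglia-like nuclei (-2.40), as did Arrdc2 in microglia-like (-0.74) and Arl4d in precursor-like nuclei (-0.85). Free RNA of the ImP 4 glia could raise these genes in other classes too, so the medians do not single out this explanation. The raised glucocorticoid level is a hypothesis from a single library, and clusters 54 and 58, which hold most of these glia in ImP 4, were not split from it.

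More fibroblast-like nuclei in both ImP libraries went with more Mgp in neuron-like nuclei. Free RNA in the proportions of fibroblast-like nuclei was argued against as the source of Mgp, since the other 206 genes typical of them gained on median 4.931% of the CPM that the gain of Mgp predicts in neuron-like nuclei (95% bootstrap interval 2.23 to 12.9%). More blood vessel with its cell types in unchanged proportions was argued against for the nuclei, since the log2 ratio of the endothelial-like share was 0.2139 (SE 0.323) against 2.57 for fibroblast-like nuclei. Vessel of a kind rich in fibroblasts stayed open, with a mural-like log2 ratio of 0.5868 (SE 0.359) from few nuclei, and so did more tissue from the base of the brain, as pituitary-like nuclei were at 0.1478% in ImP 3, with an interval of 0.0890 to 0.231% that overlaps that of vehicle 1, and an effect of ImP on meningeal or vessel-associated cells was not tested. Free RNA of fibroblasts in other proportions than in their nuclei stayed open for Mgp, since no such profile was measured and 207 fibroblast-typical genes had a median log2 ratio of 0.0902 in neuron-like nuclei (95% bootstrap interval 0.0468 to 0.122) and 8 fibroblast markers 0.37, 7 of them above 0.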

How the results depend on the processing

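The fits with another clustering seed, without the neuron clusters skewed to 1 library and without pituitary-like nuclei, and the tests of unnamed clusters, were chosen after seeing the data. The clustering in an earlier numerical environment had also been seen. In fits without 1 library the lone library of a group is assumed to vary like the others. The cause of the shifts below was not tested. In simulated microglia-like sums edgeR recovered 41 of 100 changes of 2-fold and 81 of 100 of 4-fold, against 72 and 86 in neuron-like sums.

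Counts of genes changed by ImP moved by over 1.5 times as follows. With DESeq2 they were 390 in all nuclei, 275 in neuron-like, 180 in GABAergic, 136 in glutamatergic, 11 in oligodendrocyte-like, 13 in precursor-like and 0 in microglia-like nuclei, and 1 for the interaction. With no filter on low counts they were 2, 3, 213, 118, 263 in astrocyte-like, 199 in oligodendrocyte-like, 135 in precursor-like and 15 in microglia-like nuclei, and 30 for the interaction. With a minimum count of 30 they were 0 in neuron-like and 36 in microglia-like nuclei. At 200 genes per nucleus they were 2 in GABAergic and 0 in microglia-like nuclei, and at 1000 genes per nucleus 1 in all, 32 in astrocyte-like, 6 in oligodendrocyte-like and 44 in precursor-like nuclei. At most 1% mitochondrial UMIs gave 0 in neuron-like, 29 in GABAergic, 10 in glutamatergic, 38 in astrocyte-like, 38 in oligodendrocyte-like and 24 in precursor-like nuclei, and 0 shares. With no doublets removed there were 1 in all, 2 in GABAergic, 2 in glutamatergic and 20 in precursor-like nuclei. Clustering at resolution 2 gave 0 in glutamatergic nuclei, library-centred clustering 2 in GABAergic and 3 in microglia-like nuclei, and another seed 2 in GABAergic, 2 in glutamatergic and 13 in microglia-like nuclei. Counts thinned to the lowest library gave 2 in glutamatergic and 37 in precursor-like nuclei, and adjustment over all classes 1 in all, 2 in neuron-like, 3 in GABAergic, 2 in glutamatergic, 20 in precursor-like and 1 in microglia-like nuclei. Without genes at least 10 times higher in another class there were 0 in neuron-like, GABAergic and glutamatergic nuclei, because Mgp is such a gene. TMM factors over classes gave 3 shares. List calls numbered 0 with an estimated correlation and 1 with fry.

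Without 1 library the counts ranged from 0 to 1103 in all nuclei, 1 to 251 in neuron-like, 6 to 399 in GABAergic, 0 to 99 in glutamatergic, 3 to 610 in astrocyte-like, 0 to 483 in oligodendrocyte-like, 3 to 222 in precursor-like and 0 to 63 in microglia-like nuclei, 7 to 72 for the interaction, 76 to 111 for lists and 0 to 4 for shares. The share of neuron clusters stayed at 0. Calls in neuron clusters were 418 and, at resolution 2, 399.

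Vehicle 1 and ImP 3, and vehicle 2 and ImP 4, share a library-name prefix, whose meaning the labels do not give. With the prefix as a replicate block the counts were 809 in all, 646 in neuron-like, 692 in GABAergic, 485 in glutamatergic, 676 in astrocyte-like, 504 in oligodendrocyte-like, 182 in precursor-like and 104 in microglia-like nuclei. In neuron-like nuclei Pmch, Hcrt, Oxt, Avp and Sst then passed (adjusted p = 3.2e-04, 7.9e-05, 0.00955, 2.6e-04 and 0.00133). Libraries of the same prefix deviated together with a correlation across genes of 0.06 to 0.26 over the 8 classes, with 2 pairs too few to establish pairing. The other 2 ways to part the libraries gave 0 calls by edgeR in every class, where the prefix split had 183 to 1819 genes at an unadjusted p under 0.05 and the crossed split 94 to 222. In neuron-like nuclei the prefix split had 1819 against 1438 by treatment and in glutamatergic nuclei 1523 against 1277, and in the other 6 classes it had fewer than treatment, and 3 splits are too few for a share under 0.05.

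The direction turned for these values on the log2 scale. In neuron-like nuclei without 1 library Trh ranged from -0.054 to 0.59, Npy from -0.36 to 1.07 and Agrp from -0.017 to 0.16, each lowest without ImP 4, Nr4a1 from -0.42 to 0.24 (without vehicle 1), Egr1 from -0.27 (without ImP 4) to 0.27, Nisch from -0.068 to 0.022 (without ImP 3) and Nr3c1 from -0.033 to 0.035 (without vehicle 1). Without ImP 4 Nr4a1 was 0.013, without vehicle 2 Egr1 was -0.016, and at 1% mitochondrial UMIs Egr1 was -0.043. Nr3c1, at -0.0001 in the reported fit, was 0.0025 with DESeq2 and with RLE, 0.0093 with no filter, 0.0046 at 200 genes, 0.0114 at 1% mitochondrial UMIs, 0.0029 with doublets kept, 0.0001 with the block, 0.0111 without genes of other classes, 0.0304 without ImP 3 and 0.0085 without skewed clusters. At 1% mitochondrial UMIs the share ratio was -0.36 for astrocyte-like, -1.05 for endothelial-like, 0.031 for neuron-like, 0.34 for newly formed oligodendrocyte-like, -0.29 for precursor-like and -0.15 for unnamed nuclei. For the share of nuclei: astrocyte-like the ratio was -0.069 at 1000 genes per nucleus and -0.0004 with TMM, and precursor-like -0.013 with TMM. Newly formed oligodendrocyte-like shares were 0.0013 at resolution 2, 0.0077 with another seed and 0.0010 without vehicle 2, and oligodendrocyte-like shares 0.024 without pituitary-like nuclei and 0.0094 without vehicle 1. Without 1 library the ratios ranged from -0.16 to 0.054 (without ImP 4) for newly formed oligodendrocyte-like, -0.063 to 0.040 (without ImP 4) for oligodendrocyte-like, -0.01 (without ImP 3) to 0.40 for endothelial-like and -0.81 (without ImP 4) to 1.88 for tanycyte-like nuclei.

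Over named genes and all alternatives, 1006 values kept their direction and side of the threshold, 153 passed it anew, 65 no longer passed and 20 turned, and for shares of classes these were 138, 6, 2 and 18.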

Other observations

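The tests of unnamed clusters by number were chosen only after the result had been seen. Unnamed cluster 47, led by genes such as Slit2, Spag16 and Rfx3 that include genes of ciliated ependymal cells and tanycytes, held 175, 214, 233 and 309 nuclei in vehicle 1, vehicle 2, ImP 3 and ImP 4. By edgeR 0 of 6837 genes passed there, with 611 at an unadjusted p under 0.05 and 0 by DESeq2. Unnamed cluster 50, with markers of oligodendrocytes and of another class, held 32, 36, 36 and 34 nuclei, and 3 of 2458 genes passed, Pcsk1n, Lsamp and Oxt, with 2 higher and 1 lower in ImP, 204 at an unadjusted p under 0.05 and 0 by DESeq2.

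Tanycyte-like nuclei, which line the floor of the ventricle, numbered 11, 43, 18 and 93 in the same order, and were tested only with doublets kept, where 0 of 7930 genes passed by edgeR and 579 had an unadjusted p under 0.05. Mural-like nuclei were tested only at a minimum of 200 genes, where 5 of 312 genes passed and 37 had an unadjusted p under 0.05. Neuron cluster 29, whose leading genes include Ntng1, a gene strong in thalamus, held 132, 4, 33 and 1 nuclei. Pituitary-like nuclei formed cluster 55, led by Pomc, Cga, Gh and Prl, with 3, 2, 14 and 233 nuclei, clusters 56 and 57, led by Prl and Pou1f1, and cluster 59, led by Fshb and Gnrhr, with 49 nuclei in ImP 4 and 0 in the other 3 libraries.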
